A study of Mus musculus with 24 samples.

How the data were processed

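Gene expression was measured in the prefrontal cortex of 24 male mice aged 8 weeks on a C57BL6/J background, 12 heterozygous for the Df(16)A deletion and 12 wild-type littermates. Per the labels' protocols, total RNA was extracted with a miRNeasy kit, 100 ng of it was turned into biotin-labelled cDNA with a whole-transcript sense labelling kit, and the product was hybridised to an Affymetrix array. The kit keeps short RNA, and the labelling does not select polyadenylated RNA.

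The deposited table holds log2 expression values, 1 per probe set and mouse, for 35556 probe sets. The submitters' processing notes name RMA (robust multi-array average) as the method the authors used; its version, the background and normalization steps and the genome build are not given in the sources used here. The values lay between 1.82 and 14.49 in the 24 columns and the medians of the arrays between 6.71 and 6.82. That range is the ground for reading the deposited values as log2. The series text speaks of differences at the level of exons. The table holds 1 value per probe set with a gene annotation, so values per exon were not analysed here. The table gives no detection call and no background level, so no gene could be called absent. RMA compresses fold changes of dim probe sets, because background signal adds to both genotypes.

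Probe sets were named through the platform annotation supplied with the series. Of the 35556 probe sets, 21219 had 1 gene symbol, 1880 had several and 12457, control probe sets among them, had none listed here. A gene was represented by its probe set with 1 symbol; for the 1386 genes with several such probe sets the brightest, by its mean over the 24 arrays, was used. This gave 18821 genes, of which 18791 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6. That table was used for names, for the chromosome and for which genes neighbour each other. No position is printed, because the build behind the probe sets is not named.

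Mutant and wild-type mice were compared gene by gene with limma 3.58.1 (lmFit and eBayes, genotype as the sole term) in R 4.3.3. P-values were adjusted over the 18821 genes by the Benjamini-Hochberg method with a threshold of 0.05. Each adjusted p-value given for a gene comes from that fit unless another is named. Standard errors are the moderated ones. Gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over 40 lists. Per-mouse means were compared by a two-sided permutation test with 100000 resamples. On data simulated with the means and spreads of these genes, the limma step on 18821 genes recovered 58.2% of genes changed by 0.2 on the log2 scale. It recovered 97% of those changed by 0.4 and 100% of those changed by 0.8, with 5 false calls among 175. The simulated genes were drawn independently of each other, without outlying arrays, so these rates need not hold for the real arrays.

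The gene lists, the design and the alternatives were fixed before the data were examined, unless stated otherwise. The lists held the genes of the deleted interval, its neighbours on both sides, Emc10, miRNA processing and host transcripts, the endoplasmic reticulum membrane complex, mitochondrial and ribosomal genes, synaptic, channel, axon, Wnt, calcium-store, stress, glucocorticoid, circadian, interferon, cell-cycle and immediate early genes, and markers of cortical cell types, blood and neighbouring brain regions. A further list, of all genes whose symbol is that of a miRNA precursor, was fixed by its naming pattern. Genes were named by a rule set in advance: every measured gene of the interval, Emc10, the 12 genes outside the interval with the smallest p in each direction among those past the threshold, and up to 4 members with the smallest p of each list described. Genes named outside that rule are said to be so.

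Genotypes share replicate numbers 1 to 12 in the labels, but nothing says that a number marks a litter. The correlation of deviations from the genotype means between mice of the same number ranged from -0.08 to 0.31, with a median of 0.10. Between mice of different numbers the median was -0.01, so some structure shared by mice of the same number is possible. The main fit did not treat the numbers as pairs, and a replicate block was run as an alternative. The labels also carry a running array number, 1 to 24, over which the genotypes alternate irregularly; arrays 1 to 12 and 13 to 24 were analysed separately as a check, with 7 and 5 mutants. The highest correlation between arrays was 0.997 and no columns were identical, so each array was counted as 1 mouse. The labels do not state that every array is a separate animal beyond naming it a replicate. Alternatives covered quantile normalization, median centring, moderated variances with a trend, array weights, 2 filters on dim genes, the mean of all probe sets of a gene, all probe sets tested, a replicate block, the array number and the leading residual components as terms, the array subsets, and leaving out each array in turn. The number of arrays, not a read depth, limits the precision.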

Results

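The prefrontal cortex of Df(16)A heterozygous mice was profiled to find transcripts whose level differs from that of wild-type littermates. Df(16)A is an engineered deletion on mouse chromosome 16 that removes a single copy of a segment corresponding to the human 22q11.2 microdeletion, a strong genetic risk factor for schizophrenia. The data comprise 24 arrays, 12 per genotype, all from males aged 8 weeks, with RMA values on the log2 scale. The arrays were alike, with pairwise correlations across 18821 genes between 0.994 and 0.997. The first principal component held 14.7% of the variance and differed in mean between the genotypes, at -3.69 ± 7.93 (SD, n = 12) in mutants and 3.69 ± 5.51 in wild types (permutation test, two-sided, p = 0.0146). The mutant arrays of replicates 9, 5 and 10 lay farthest out on it and are called the 3 outlying arrays below. By mean correlation with the other arrays, replicate 9 was low (0.9954), as was the wild type of replicate 11 (0.9954), which was kept. Mutant replicates 5 and 10 (0.9961) lay above the wild type of replicate 3 (0.9959). Leaving out only mutants from the mutant end of this component may also remove part of the genotype difference.

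The first comparison concerned the genes of the deleted segment, which also checks the genotype labels. Of 26 measured genes of the interval, 20 fell in mutants and none rose. The median log2 fold change over 25 of them, with the precursor Mir185 left aside, was -0.64, a fold of 0.642. Adjusted over the list alone, 22 fell. Averaged over those 25 genes in each mouse, the level was 7.87 ± 0.03 (SD, n = 12) in mutants and 8.42 ± 0.03 in wild types. The highest mutant, at 7.95, lay below the lowest wild type, at 8.37 (permutation test, two-sided, p = 1e-05, the smallest that the resamples can give).

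The largest decreases were in Slc25a1, the mitochondrial citrate carrier, with a log2 fold change of -0.88 ± 0.03 (SE), and in Ufd1, a cofactor in the removal of ubiquitinated proteins, with -0.88 ± 0.02 (limma, adjusted p = 3.42e-17 and 7.29e-20). Other mitochondrial genes of the interval fell as well. Mrpl40, a protein of the mitochondrial ribosome, changed by -0.76 ± 0.03, Prodh, which degrades proline, by -0.71 ± 0.05, and Txnrd2, the mitochondrial thioredoxin reductase, by -0.64 ± 0.04. Among genes with known roles at neurons and synapses, Zdhhc8, a palmitoyltransferase, changed by -0.80 ± 0.03 and Rtn4r, the Nogo receptor, by -0.68 ± 0.05. Dgcr2, an adhesion receptor-like protein, changed by -0.80 ± 0.02, and Arvcf, a catenin, by -0.61 ± 0.04. Cldn5, the tight-junction protein of brain endothelium, changed by -0.63 ± 0.04.

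Dgcr8, which encodes the RNA-binding partner of Drosha in the cleavage of primary miRNA transcripts, fell from 8.79 ± 0.05 (SD, n = 12) to 8.26 ± 0.08, a log2 fold change of -0.54 ± 0.03 (limma, adjusted p = 5.2e-13). The other decreases of the same order were in Ranbp1 (-0.77), Tango2 (-0.77), Ess2 (-0.73), Trmt2a (-0.68), Hira (-0.64), Dgcr6 (-0.62) and 2510002D24Rik (-0.82). Smaller decreases were measured in Cdc45 (-0.30) and Gnb1l (-0.27). In 19 of the 20 genes that fell, all 12 mutants lay below all 12 wild types; the exception was Cdc45, with 10 mutants below.

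The 6 interval genes that did not pass the test were Tssk1 (-0.06), Tssk2 (-0.03), Gsc2 (0.06), Vpreb2 (-0.001), Tbx1 (-0.17, adjusted p = 0.119) and Mir185 (-0.16, adjusted p = 0.32). Their median level was 5.99, against 8.86 for the 20 genes that fell and 7.58 for all genes; Mir185, at 7.77 in wild types, was brighter, and Tbx1 (6.56) lay above the called genes Cdc45 (6.25) and Gnb1l (6.26).

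**Figure D1:**
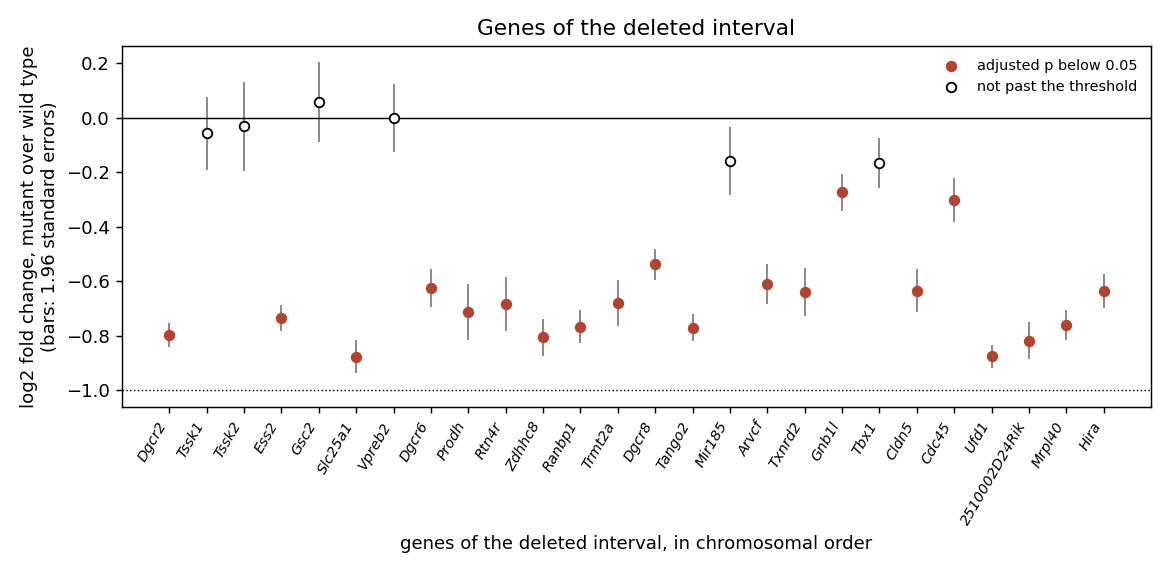
Log2 fold change of each measured gene of the deleted interval (vertical axis, mutant over wild type, 12 mice each; bars are 95% intervals from the limma standard errors) in chromosomal order (horizontal axis), with the level of a halved signal dotted at -1. The 20 genes past the threshold (filled) lie between -0.88 and -0.27 and the 6 others (open) between -0.17 and 0.06.

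Outside the listed genes, the neighbourhood of the deletion was examined for further changes. Car15, a carbonic anhydrase gene next to Dgcr2, fell by 0.57 on the log2 scale and 4933432I09Rik, which lies between Dgcr2 and Hira, by 0.53 (limma, adjusted p = 1.58e-09 and 0.000591). Of 22 measured genes listed on the proximal side and 21 on the distal side, none passed the test over all genes; Lztr1 had a log2 fold change of -0.08 (adjusted p = 0.101) and Klhl6 one of 0.18 (adjusted p = 0.217). Adjusted over the list alone, 1 proximal gene was lower. Within 10 Mb of the interval, 19 of 172 genes (11%) had an unadjusted p under 0.05, against 11.8% of the 18622 others (Fisher's exact test, two-sided, p = 0.905). The neighbouring genes past the adjusted threshold were Car15 and 2610318N02Rik, the latter higher by 0.33 ± 0.05, and the latter was chosen after its value was seen. 2610318N02Rik has 2 probe sets, of which the brighter was used, and its place on chromosome 16 comes from the gene table. That probe set is numbered between those of Egr1 and Csf1r, genes of chromosome 18. Its signal may therefore not come from beside the deletion.

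The second comparison asked which genes other than those listed for the interval differed. There were 100 genes higher and 23 lower in mutants. The 23 include 4933432I09Rik, which lies within the deleted segment, and Car15 next to it; with both counted in the interval, a setting chosen after the data were seen, 21 were lower. Of the 100, 59 were miRNA precursor genes, where 1.61 would be expected from their share of the genes (Fisher's exact test, two-sided, p = 4.26e-81). That test counts each precursor as independent, although some are transcribed together, so its p-value is too small. Unadjusted p-values under 0.05 were found for 2245 genes, against 941 expected by chance. The median log2 fold change of all genes was -0.001.

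Emc10, also known as 2310044H10Rik, a subunit of the endoplasmic reticulum membrane complex and the gene known from earlier work on this mouse line, had the smallest p-value outside the interval. Its level rose from 10.81 ± 0.06 (SD, n = 12) in wild types to 11.20 ± 0.04 in mutants, a log2 fold change of 0.39 ± 0.02 (SE) and a fold of 1.31 (limma, adjusted p = 1.43e-11). All 12 mutants lay above all 12 wild types. The log2 fold change was 0.35 over arrays 1 to 12 and 0.44 over arrays 13 to 24. Of 9 other measured genes of the same complex none passed the test, and all 9 had values below 0, with a median of -0.04 (camera, adjusted p = 0.0544; adjusted p = 0.52 with an estimated correlation).

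A whole-transcript array row named to a miRNA precursor reports RNA that contains that sequence, and does not separate a primary transcript from the hairpin cut from it; it does not measure the mature miRNA. Of 303 measured precursor genes, 59 rose, none fell and 244 did not pass. Adjusted over the list alone, 107 rose and 1 fell. The median over the list was 0.11, and 87.1% of its members lay above 0, against 48.4% of the other genes outside the interval. The list's shift had a camera adjusted p of 2.6e-39, and of 0.000272 with an estimated correlation. The mean over the precursors was 5.82 ± 0.03 (SD, n = 12) in mutants and 5.65 ± 0.07 in wild types, and the lowest mutant, at 5.78, lay above the highest wild type, at 5.75 (permutation test, two-sided, p = 1e-05, the smallest that the resamples can give).

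Mir137, a miRNA gene at a locus associated with schizophrenia in humans, had the largest of these changes, from 6.62 ± 0.20 (SD, n = 12) to 7.78 ± 0.19, a log2 fold change of 1.15 ± 0.08 (SE) and a fold of 2.22 (limma, adjusted p = 3.39e-11). Mir101a rose by 0.84 ± 0.07, and both loci of miR-138, a miRNA known from dendritic spines, rose, Mir138-2 by 0.77 ± 0.06 and Mir138-1 by 0.70 ± 0.07. Of the loci of miR-9, a miRNA abundant in the brain, Mir9-2 rose by 0.41 ± 0.03 and Mir9-3 by 0.55 ± 0.06. The third locus, Mir9-1, named after its value was seen, rose by 0.64. The loci of miR-124, a neuronal miRNA, were also looked up after their values were seen: Mir124a-1 rose by 0.68, Mir124a-2 by 0.48 and Mir124a-3 by 0.37. In all the precursors that passed, the log2 fold change lay between 0.21 and 1.15, with a median of 0.46.

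On chromosome 12, the imprinted region around Meg3 and Rian holds a cluster of miRNA genes that are transcribed together. Of its 36 measured precursors 16 rose, with a median over the cluster of 0.32. Mir412 rose by 0.75 ± 0.07, Mir485 by 0.65 ± 0.07, Mir369 by 0.65 ± 0.06 and Mir409 by 0.61 ± 0.07. The precursors elsewhere in the genome numbered 267, of which 43 rose, with a median of 0.09. Meg3 itself, the long noncoding RNA of the cluster, had a log2 fold change of 0.09 ± 0.03 (adjusted p = 0.188) and Rian, named outside the rule for named genes, one of 0.02 ± 0.06 (adjusted p = 0.926).

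Of 8 measured transcripts listed as hosts of miRNAs, 2 rose and 6 did not pass; adjusted over the list alone, 3 rose. A330023F24Rik, a noncoding RNA, rose by 0.50 ± 0.07 and Mir100hg, the host of a let-7 and miR-125 cluster, by 0.24 ± 0.04 (limma, adjusted p = 2.11e-05 and 0.000736). Dleu2 had a value of 0.15 ± 0.08. The list's camera adjusted p was 0.000503, and this call was lost with an estimated correlation (adjusted p = 0.0779 with an estimated correlation). Of 25 other genes of miRNA processing and function, none passed the test, with a median of -0.005. Xpo5, the exporter of precursors, had -0.06 ± 0.03 and Adarb1, an RNA-editing enzyme, -0.07 ± 0.03. In the other direction, Tnrc6c had 0.07 ± 0.03 and Lin28a 0.15 ± 0.06. The 3 outlying arrays did not carry the precursor result: without them, a setting chosen after the data were seen that left 9 mutants and 12 wild types, 64 precursors rose.

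**Figure D2:**
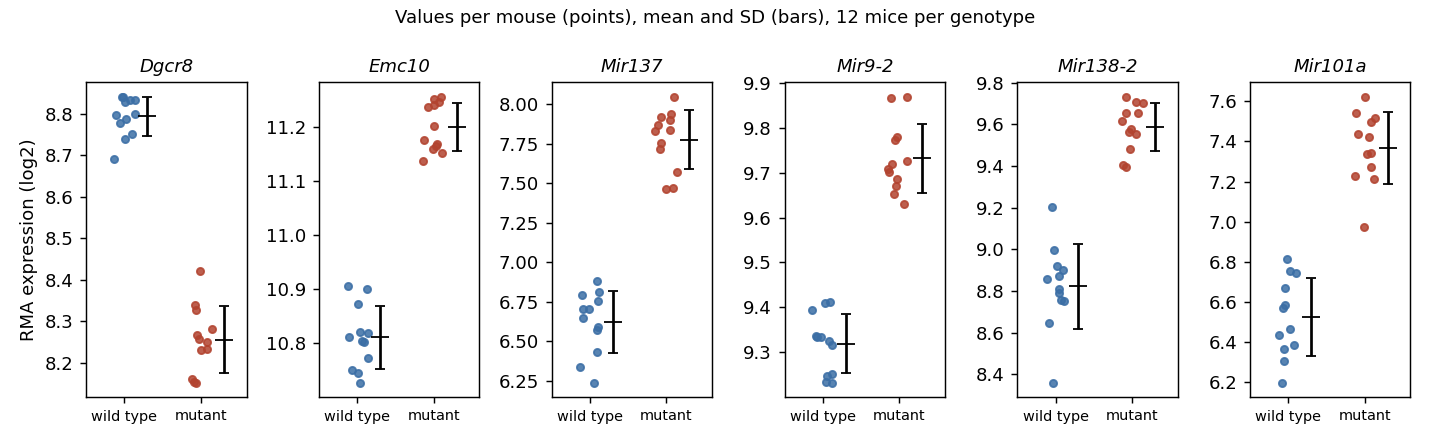
Expression of 6 genes in each mouse (points; vertical axes, RMA log2 values, which start at different levels) with the mean and SD of the 12 mice per genotype. All 12 mutants lie below the wild types for Dgcr8 and above them for Emc10, Mir137, Mir9-2, Mir138-2 and Mir101a.

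**Figure D3:**
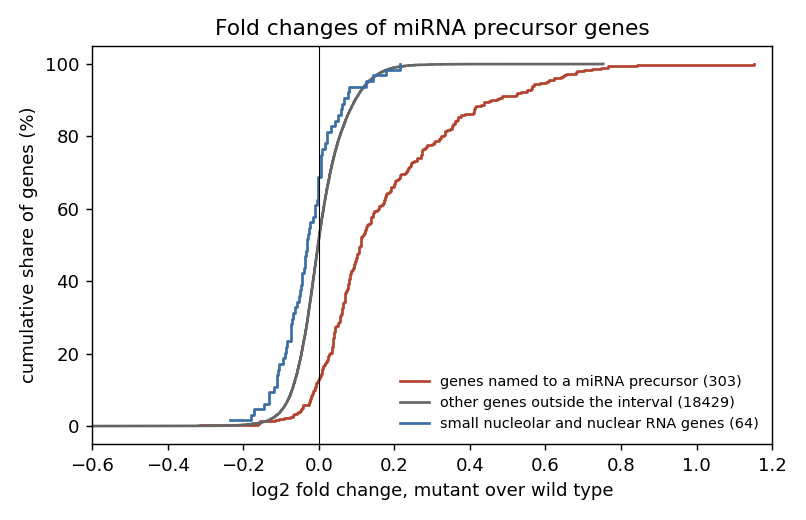
Cumulative share of genes (vertical axis, percent) by log2 fold change, mutant over wild type (horizontal axis; 12 mice each), for 303 miRNA precursor genes, 64 small nucleolar and nuclear RNA genes and the remaining genes outside the interval. The curve of the precursors, with a median of 0.11, lies to the right of the others, and the median of the small nucleolar and nuclear RNA genes was -0.03.

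Of the 41 genes that rose and were neither precursors nor in the interval, those named by rank were Emc10 and a, the nonagouti gene, which encodes a signalling protein that controls coat colour. The nonagouti gene rose from 5.38 ± 0.17 (SD, n = 12) to 6.13 ± 0.19, a log2 fold change of 0.75 ± 0.07 (SE), with all 12 mutants above all 12 wild types (limma, adjusted p = 5.75e-08). The median over the 41 genes was 0.23.

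The 23 genes that were lower had smaller changes, with a median of -0.17; the range was -0.57, for Car15, to -0.09. After Car15, the smallest p-values were those of H4c4, a histone H4 gene, which fell by 0.20 ± 0.03 (SE), and Tmem44, a membrane protein gene on chromosome 16, by 0.29 ± 0.05. Phip, which encodes a chromatin-binding protein, fell by 0.15 ± 0.03, and Peg10, an imprinted gene derived from a retrotransposon, by 0.25 ± 0.05. Cbln4, a secreted synaptic organiser, fell by 0.29 ± 0.06, and Gid4, a subunit of a ubiquitin ligase, by 0.12 ± 0.02. Further decreases were in the histone genes H4c14 (-0.14) and H2aw (-0.15), in Stip1, a co-chaperone (-0.10), and in Actl6a, a subunit of chromatin remodelling complexes (-0.14). The count of 23 was less stable than that of genes that were higher: it was 13 without the 3 outlying arrays and 36 without the mutant of replicate 4.

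Of 45 genes of oxidative phosphorylation none passed the test; 38 had values below 0, with a median of -0.03 (camera, adjusted p = 0.00159; adjusted p = 0.52 with an estimated correlation). Cox7a2 had -0.11 ± 0.04 and Atp5a1 -0.05 ± 0.02. Of 61 genes of the mitochondrial ribosome outside the interval none passed, 45 lay below 0 and the median was -0.03 (camera, adjusted p = 0.00647; adjusted p = 0.565 with an estimated correlation); Mrpl32 had -0.18 ± 0.05. Without the 3 outlying arrays the camera adjusted p was 0.00134 for oxidative phosphorylation and 0.104 for the mitochondrial ribosome. Of 22 genes of citrate and proline metabolism none passed (camera, adjusted p = 0.143), and neither did any of 47 genes of the cytosolic ribosome (camera, adjusted p = 0.0787).

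Of 22 interneuron markers 1 rose and 21 did not pass; adjusted over the list alone, 2 rose. Nos1, the neuronal nitric oxide synthase, rose by 0.20 ± 0.04 (limma, adjusted p = 0.0227). Reln had 0.08 ± 0.03, Dlx6 0.15 ± 0.06 and Vip 0.11 ± 0.06. The median over the list was 0.04 (camera, adjusted p = 0.00492, and 0.42 with an estimated correlation). Without the 3 outlying arrays the camera adjusted p of the interneuron list was 0.00126, and 0.345 with an estimated correlation. Of 26 genes of dopamine and serotonin signalling none passed, with a median of 0.03 (camera, adjusted p = 0.0441; adjusted p = 0.307 with an estimated correlation); without the 3 outlying arrays the camera adjusted p was 0.104. Ppp1r1b, which encodes the phosphatase inhibitor DARPP-32, had 0.13 ± 0.04. The list of 18 stress and unfolded-protein genes had a median of -0.03 and no member that passed (camera, adjusted p = 0.0467; adjusted p = 0.52 with an estimated correlation). With the first residual component as a term its camera adjusted p was 0.059. Without the 3 outlying arrays it was 0.00377, and 0.438 with an estimated correlation.

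Of 40 genes of axon growth and guidance, 1 rose: Slit3, a guidance ligand whose gene overlaps or lies within 20 kb of that of Mir218-2, by 0.14 ± 0.03 (limma, adjusted p = 0.0324). For the list, the camera adjusted p was 0.294. Without the 3 outlying arrays neither Nos1 nor Slit3 passed. No member passed the test among 32 synaptic vesicle genes, 36 glutamate postsynaptic genes, 14 GABA synapse genes, 34 ion channel genes, 12 calcium-store genes, 34 genes of Wnt and GSK3 signalling, 20 cortical layer markers, 23 immediate early genes, 19 interferon-response genes, 20 cell-cycle genes, 13 glucocorticoid-response genes and 13 circadian genes, and the camera adjusted p was above 0.05 for each of these lists. Adjusted over the list alone, 1 calcium-store gene was higher and 1 circadian gene lower. The lowest of the camera values was 0.069, for the GABA synapse genes, and for interferon-response genes it was 0.0787. For the latter list it was 0.0364 with the replicate block, 0.309 without the 3 outlying arrays and adjusted p = 0.52 with an estimated correlation.

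Markers of other cell types were followed as a measure of dissection and tissue composition. No marker passed the test among those of neurons (median -0.007), astrocytes (0.009), oligodendrocytes (-0.05), oligodendrocyte precursors (-0.04), microglia (-0.004), endothelium (-0.003), pericytes and fibroblasts (0.01), choroid plexus (0.02), striatum (0.03), olfactory bulb (-0.002) and hippocampus and thalamus (0.03), nor was the camera adjusted p of any of these lists under 0.05. Adjusted over the list alone, 1 marker of pericytes and fibroblasts was lower. All 13 oligodendrocyte markers lay below 0 (camera, adjusted p = 0.069). The 5 blood markers had a median of -0.46 and none passed, with all 5 below 0 (camera, adjusted p = 0.0245; adjusted p = 0.52 with an estimated correlation); without the 3 outlying arrays the camera adjusted p was 0.0986. The granulocyte gene Ngp varied among wild types, at 7.24 ± 1.44 (SD, n = 12) against 6.04 ± 0.67 in mutants.

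The fold changes measured in arrays 1 to 12 and in arrays 13 to 24, which share no mouse, were compared across genes, which are not independent replicates. For the 26 interval genes Pearson's r was 0.976 and Spearman's rho 0.946. For the 302 precursors outside the interval r was 0.632 and rho 0.447. For the 18493 remaining genes r was 0.175 and rho 0.17, and 56.5% of them had the same sign in both sets of arrays. Each set alone called 35 genes higher and 4 lower outside the interval.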

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

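The gene-level comparison used probe sets with a single gene symbol. When every probe set was tested (an alternative planned before the data were examined), some of those it had left aside passed the threshold. Among the 1880 probe sets named to several genes, 16 were higher in mutants and 6 lower. Among the 12457 with no gene listed here, 9 were higher and 4 lower. These are counts of probe sets and not of further genes. Of the 6 lower probe sets with several symbols, 1 includes a gene of the interval and 2 hold identical values. The positions of the others were not examined, but some are numbered among probe sets of known place. Several of the higher ones with several symbols, at 0.51 to 0.96, are numbered between Meg3 and Mir370 of the chromosome 12 cluster. Of those with no gene listed, one at -0.80 is numbered between Mir185 and Tbx1 and one at -0.63 between Gnb1l and Cldn5. The counts of precursors and interval genes given above leave such probe sets out and may be too low.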

How the results depend on the processing

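All alternatives were planned before the data were seen except leaving out 3 outlying arrays, counting Car15 and 4933432I09Rik in the interval and leaving out Car15 in the test of neighbours. The rise of Emc10 kept its direction and its side of the threshold under all alternatives run. Of the interval genes, 20 fell in the main analysis, 19 over arrays 1 to 12, 18 over arrays 13 to 24 and 17 without the lower 50% of genes, which leaves fewer of them to test. The Emc10 log2 fold change ranged from 0.35 to 0.44 with a highest adjusted p of 6.97e-05. The interval median moved to -0.68 without the lowest 25% of genes, -0.73 without the lower 50% and -0.67 over arrays 1 to 12. The interval mean per mouse differed by -0.55 between genotypes, by -0.59 without the lowest 25% of genes and by -0.73 without the lower 50%; these filters remove the dim interval genes. The number of genes higher outside the interval was 48 without the lower 50% of genes, 35 in each set of 12 arrays and 230 with 3 residual components as terms. The number of lower genes was 46 with a variance trend, 46 without the lowest 25%, 50 without the lower 50%, 15 with every probe set tested, 37 with the array number as a term, 49 with the first residual component and 118 with 3. It was 4 in each set of 12 arrays and 13 without the mutants of replicates 9, 5 and 10. The cause was not tested, except that subsets hold fewer mice. Leaving out each array in turn gave 20 interval genes throughout, an interval median of -0.66 to -0.63, 82 to 108 higher genes, 17 to 36 lower genes (36 without the mutant of replicate 4) and an Emc10 value of 0.38 to 0.40. The rise of the host transcripts was lost with an estimated correlation (adjusted p = 0.0779). The correlation of the 2 sets of arrays outside the interval was 0.245, and 0.347 without the lower 50% of genes. With the replicate block, 110 genes were higher and 17 lower outside the interval and 55 precursors rose, and the interferon-response list passed the threshold (camera, adjusted p = 0.0364, against 0.0787; 0.309 without the 3 outlying arrays and adjusted p = 0.52 with an estimated correlation); 109 of its 147 calls were shared with the main 143. In the check of pairing, 2 of 12 mutants correlated best with the wild type of their own number. The test of neighbours on chromosome 16 stayed above the threshold with 5 Mb (p = 0.779) and with the adjusted threshold (p = 0.307), and without Car15 (p = 1 at the adjusted threshold). With Car15 and 4933432I09Rik counted in the interval, it had 22 lower genes and 21 others were lower.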

Other observations

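In this part the test on short RNA, the test on gene density and the list of histone genes were chosen after the results were seen. Several protein-coding genes outside the interval that rose were not precursors and were named after their values were seen. Serpina3n, a protease inhibitor gene known from reactive astrocytes, rose by 0.30 on the log2 scale, Esr1, the oestrogen receptor alpha, by 0.25, Tacr2, a tachykinin receptor, by 0.37, and Alox8, a lipoxygenase, by 0.24. Doc2b, a calcium sensor of vesicle release, rose by 0.28. Among genes that fell, 3 of 33 measured histone genes passed the test (H4c4, H4c14 and H2aw), 23 of 33 lay below 0 and the median was -0.04. For this list, chosen after the calls were seen, the camera p was 2.01e-05 with the preset and 0.0259 with an estimated correlation. The list holds the 3 called genes that prompted it and the p-values are unadjusted, so they are no independent support. Histone genes have near-identical copies, so which copy changed is uncertain. Peg10 and Plagl1, both imprinted genes, fell by 0.25 and 0.14; Plagl1 was named after its value was seen. Mir320 and Mir484, miRNAs known to mature without Dgcr8, were named outside the rule for named genes. Their log2 fold changes were -0.02 ± 0.06 (SE) and 0.06 ± 0.04, and neither passed the test. Of the 303 precursors, 244 did not pass, so these 2 values do not set such miRNAs apart.

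Among 100 splits of the 24 mice into 12 and 12, the real one included, only the real split reached each of its 4 counts. These were 20 interval genes (highest other 0) and 59 precursors (highest other 0). Outside the interval they were 100 genes higher (highest other 2) and 23 lower (highest other 2). A share of 1 in 100 is the smallest that these splits can give, so chance is made unlikely but is not excluded. The splits took no account of replicate or array numbers, and the 23 include 4933432I09Rik and Car15.

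The rise of miRNA precursors is a pattern for which 2 technical explanations were tested. A higher yield of short RNA in mutants would raise other short RNAs. The median of 64 small nucleolar and nuclear RNA genes was -0.0318 against 0.11 for the precursors, and none of the 64 passed the test, which argues against it. The 95% bootstrap interval of that median, -0.046 to -0.004, resampled genes and not mice, so it leaves out the spread between mice. A general drift of dim probe sets is argued against by 10000 random gene lists matched on level, whose highest median was 0.0335. A candidate explanation, as a hypothesis, is less cleavage of primary transcripts with less Dgcr8: within mutants the mean of the called precursors and the Dgcr8 level had r = -0.028 (n = 12, permutation p = 0.932, adjusted 0.932; rho = -0.17, permutation p = 0.587; r = 0.03 without the 2 farthest mice), and within wild types r = 0.30 (permutation p = 0.343, adjusted 0.686; rho = 0.28, permutation p = 0.377; r = 0.21 without the 2 farthest). These 2 relations leave it open, since Dgcr8 varies little within a genotype and is deleted together with the other genes of the interval, whose effects cannot be told apart from its own.

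A second pattern concerns genes beside miRNA genes: of 40 genes that rose and were compared, 11 (27.5%) lay within 20 kb of a miRNA gene of the reference table, against 7.31% of all genes compared (Fisher's exact test, two-sided, p = 9.81e-05). Here "beside" includes genes that overlap or contain the miRNA gene, which were not told apart from neighbours. Of these 11, 4 lay beside called precursors: Spaca6 beside Mirlet7e and Mir125a (0.33), Nup93 beside Mir138-2 (0.29), Aopep beside Mir23b, Mir27b and Mir24-1 (0.25) and Slit3 beside Mir218-2 (0.14). All but Slit3 were named after their values were seen. The rest of the 11 lay beside miRNA genes that were not among the called precursors. Those calls cover only probe sets with 1 symbol, so a miRNA gene beside the rest may still have risen. Probe sets with several symbols, numbered directly after that of A330023F24Rik, were higher by 0.76 and 0.44 (limma with every probe set tested, adjusted p = 6.43e-07 and 0.000193). The 40 genes include the listed host A330023F24Rik and leave out Mir100hg because of its name. Gene-dense surroundings are argued against by 10000 random sets of 40 genes matched on the number of genes within 100 kb, with a median of 3 genes beside a miRNA gene and a share of 2e-04 with as many as 11; the 0 of 21 genes that fell decide nothing, since 1.54 would be expected (Fisher's exact test of higher against lower calls, two-sided, p = 0.0109). A shared transcript with a precursor that rose stays open, with a difference of medians of 0.026 between 33 genes beside called precursors (0.026) and 218 beside precursors not called (-0.0002; permutation test, two-sided, p = 0.0274), a small difference in which 4 of the 33 genes passed the test. That permutation moved genes and not mice, and some genes lay beside the same precursor, such as Wdr6, Ndufaf3, Qrich1 and P4htm beside Mir191. Its p-value may therefore be too small, and the precursors were called on the same arrays. Which strand these genes share with the precursors was not examined.

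The third pattern is the nonagouti gene, higher in 12 of 12 mutants. Skin or hair tissue in the mutant samples is argued against by 12 skin marker genes, with a median of 0.0189 and none past the threshold. The 95% bootstrap interval of that median, 0.001 to 0.06, resampled genes and not mice. A linked strain segment stays open: of 78 genes within 2 Mb, 13 had an unadjusted p under 0.05 and none passed the adjusted threshold (odds ratio 1.57, 95% interval 0.794 to 2.89, Fisher's exact test, two-sided, p = 0.149). Vectors used to engineer chromosomes in mice can carry an agouti coat-colour marker gene; whether the Df(16)A chromosome does is not stated in the labels and was not tested.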
